A study of Manihot esculenta with 8 samples.

How the data were processed

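Total RNA from 4 control and 4 cold-treated samples of cassava shoots was made into strand-specific libraries with a stranded total RNA kit, per the labels' protocols. The deposited table holds whole-number counts per gene ID, with 1 column per library and no scaling for depth or length. The submitters' processing notes name STAR 2.7.10a, SAMtools 1.6 and bedtools 2.30, without their role or order. The counting tool, strand setting, treatment of reads that map to several places, filters, annotation release and genome build are not given in the sources used here. Counts of overlapping or near-identical genes are uncertain for that reason. All columns matched a library by name.

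None of the 31901 IDs matched the gene table used for names, which describes the assembly M.esculenta_v8 and has 34312 rows (0 matches). The 35 gene lists chosen before the data were examined need gene descriptions and could not be tested, and neither could the comparison of noncoding with protein-coding genes or that of antisense gene pairs. Chromosome and locus numbers were read from the IDs; the numbers were used to order genes and were not checked against coordinates.

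Depth ranged from 62798223 to 100031792 counts per library. Libraries of a group were compared by a chi-square test over IDs with at least 10 counts, to look for a library deposited more than once, and none was found. Differences between cold and control were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr with the group, TMM factors, robust quasi-likelihood fit and F test, 2-sided) on the counts as deposited. P-values were adjusted by the Benjamini-Hochberg method over 26517 IDs, with a threshold of 0.05, and no replicate block was used. The common biological coefficient of variation was 0.326. TMM factors lay between 0.947 and 1.039. Standard errors were obtained from the log2 fold change and its F statistic. CPM values use these factors, and medians per library were taken on log2 of CPM plus 0.5.

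IDs were named by a rule set before the data were examined. It takes the largest changes among IDs past the threshold with a mean of at least 10 CPM and with every cold library above or below all control libraries, limited to 2 that rose and 2 that fell because no names were at hand. The 4 abundance classes use the mean CPM over all libraries. Chromosome shares were compared by Fisher's exact test, 2-sided, adjusted over all chromosomes and both directions. Order along the ID series was tested by shuffling the calls over the tested IDs 10000 times, for adjacent pairs and for the fullest window of 20 tested IDs. The position tests, the abundance classes, the IDs near 0 and the most abundant IDs were chosen after the data had been examined. The chromosome 9 stretch had been noticed in an earlier scan of runs and wider windows before the 20-ID window test was set.

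The procedure was tested on simulated data, drawn for 26517 IDs from the real means and library sizes with 200 changed IDs in the comparison of cold with control. Of the simulated IDs, 26358 passed the filter and were tested. The procedure recovered 2% of 1.5-fold, 36% of 2-fold, 76% of 4-fold and 90% of 8-fold changes, and 6 unchanged IDs were called, 5.6% of its calls. Counts were drawn independently for each ID, so the share of false calls may differ in the real libraries. Many changes below 4-fold were therefore missed in the simulation. It changed 200 IDs, while the real fit called 2425, and the adjustment of p-values is stricter when fewer IDs change. The recovered shares may therefore be lower than those of the real fit, which were not measured.

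Alternatives planned beforehand were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper quartile factors, library size only, no filter, a filter of at least 1 CPM in 4 libraries, glmTreat against a 1.5-fold change, the replicate number as a block, the 10 most abundant IDs left out, and each library left out in turn. Added after the data were examined were 1 surrogate variable from sva 3.50.0, limma-voom with library weights, and a fit of control replicates 2 to 4 against cold replicates 2 and 4. Positions, tests of explanations and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.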

Results

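Strand-specific RNA sequencing was used to compare shoots of cassava (Manihot esculenta, a tropical root crop) kept in control conditions with shoots harvested after a cold treatment. All plants were wild-type seedlings of the cultivar TM12, grown at 20 °C by day and 18 °C by night with 16 h of light, 8 h of dark and 60% humidity. The cold group was moved after 2 weeks to a room at 4 °C, in the light, and harvested 3 h later. The labels do not give the time of day at which the control shoots were taken. Each group held 4 libraries. Total gene counts were 82385404, 91699115, 96516912 and 84113457 in control replicates 1 to 4. In cold replicates 1 to 4 they were 100031792, 80595858, 62798223 and 88943518. The table held 31901 gene IDs, of which 1640 had 0 counts in all 8 libraries, and between 28280 and 28978 IDs were detected per library. Levels are given in CPM, read counts scaled to a common library size. A floor of 3 counts corresponded to between 0.03 and 0.0478 CPM, depending on the library. Nothing in the labels says that the libraries came from separate plants or pools, so the p-values measure the spread between these samples, part of which may be technical.

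The IDs are given as in the deposited table, and no name or description could be paired with them. Genes are therefore described by direction, size, abundance and the chromosome and locus numbers that the IDs carry. No genome build is named in the sources used here, and the order of loci was taken from the IDs, not from coordinates.

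The first 2 principal components of log2 CPM held 35.3% and 21.3% of the variance. The 4 control libraries lay between -83.8 and -18.4 on the first component and the 4 cold libraries between 23.4 and 72.3. Correlations between libraries were 0.94 to 0.98 within groups and 0.918 to 0.964 between groups, across genes, which are not independent replicates. The closest pair of libraries within a group still differed with a chi-square per degree of freedom of 63.4, beyond counting noise, so no library was a repeat deposit of another. This does not show whether libraries shared plant material. Control replicate 1, cold replicate 1 and cold replicate 3 held more of their counts in their 1000 most abundant IDs (37.6%, 36.36% and 38.07%) than the other 5 libraries (33.41% to 34.57%).

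The design asks which transcripts differed in abundance after 3 h at 4 °C. Of 26517 tested IDs, 2425 (9.1%) differed at an adjusted p below 0.05, with 1076 higher and 1349 lower in the cold. Risen IDs were fewer in this fit, and more of them reached the larger folds. At least 2-fold changes were found for 533 risen and 632 fallen IDs, at least 4-fold changes for 232 and 113, and at least 8-fold changes for 98 and 16. The median log2 fold change was 0.99 among risen and -0.96 among fallen IDs, and the smallest change that passed was 0.35 on the log2 scale. The 4 cold libraries lay wholly above the 4 control libraries for 1049 of the 1076 risen IDs and wholly below them for 1327 of the 1349 fallen IDs. Over all tested IDs, 5027 (19.0%) had groups that did not overlap, against 2.9% expected by chance. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The total was 1066 without control replicate 2, 1360 without control replicate 3, 1557 without control replicate 4, 1547 without cold replicate 3 and 1264 without cold replicate 4, and 1388 without the 3 libraries with the large top-1000 share. DESeq2 called 4667 IDs, and a test against a 1.5-fold change called 502. The balance of directions turned without cold replicate 2, with 945 higher and 941 lower, and 580 against 549 at least 2-fold. At least 2-fold changes in DESeq2 were 909 higher and 847 lower, and the test against a 1.5-fold change gave 253 higher and 249 lower IDs.

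**Figure D1:**
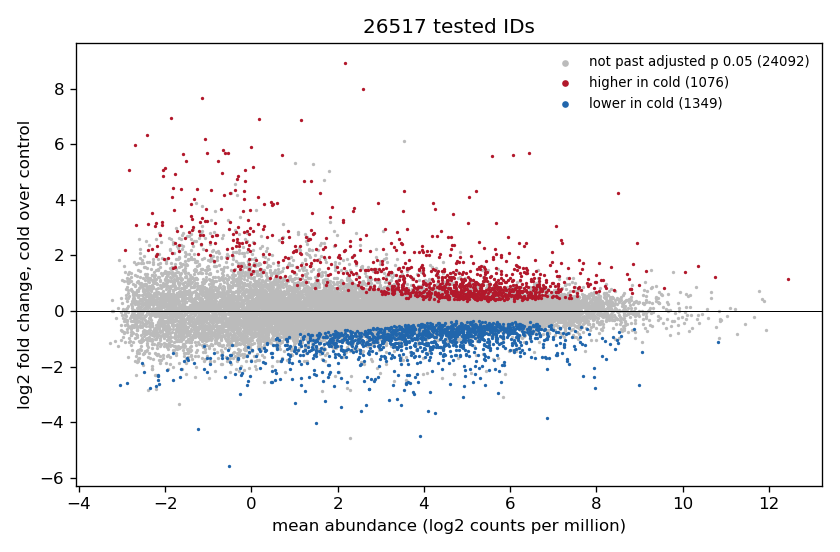
Log2 fold change of cold over control (vertical axis) against mean abundance in log2 CPM (horizontal axis) for 26517 tested IDs. The 1076 risen IDs are red, the 1349 fallen IDs blue and the 24092 IDs that did not pass an adjusted p of 0.05 grey. The median absolute log2 change of called IDs was 2.05 among the scarcest and 0.80 among the most abundant of 4 nearly equal classes. Scarce IDs need a larger change to pass, so these medians do not compare the strength of the response.

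The risen IDs together took 3.80% ± 0.19 of the counts in control and 7.54% ± 0.22 in cold libraries (SD, n = 4 each). The fallen IDs took 6.20% ± 0.30 in control and 3.02% ± 0.11 in cold libraries. Both groups were picked on these samples, so the shares describe them and are not an independent test. The tested IDs were divided by mean CPM into 4 classes of nearly equal size. In the lowest class, 210 IDs were higher and 188 lower, and the median absolute log2 change of those called was 2.05. In the second class 201 were higher and 452 lower, with a median of 1.02. In the third 305 were higher and 392 lower, with a median of 0.81, and in the highest class 360 were higher and 317 lower, with a median of 0.80. The difference in balance between the classes was not tested.

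The most abundant ID, ranked by mean CPM over all libraries, rose from 3474 ± 622 CPM in control to 7654 ± 1255 CPM in cold libraries (SD, n = 4 each). The rise itself adds to this rank. In control, the IDs of rank 2 (4807 CPM) and rank 6 (3495 CPM) had higher means. The log2 fold change of the most abundant ID was 1.14 (SE 0.25) with an adjusted p of 0.0222 in edgeR's quasi-likelihood test. The other 9 of the 10 most abundant IDs did not pass the test. The rise kept its direction in 20 alternatives, with adjusted p between 7.58e-08 and 0.188, and the adjusted p was above 0.05 in 6 of them. These include the fits without control replicate 2 (0.0529), control replicate 3 (0.0653) or control replicate 4 (0.0619).

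The ID pair with the largest rises that met the rule for named IDs carried consecutive locus numbers on chromosome 14. MANES_14G145700 rose from 3.28 ± 1.56 to 169.8 ± 117 CPM (SD, n = 4 each), a log2 fold change of 5.69 (SE 0.66) with an edgeR adjusted p of 0.00167. MANES_14G145800 rose from 2.72 ± 1.31 to 131.9 ± 89.5 CPM, a log2 fold change of 5.60 (SE 0.65) with the same adjusted p. Reads may be shared between these neighbours; how the counting treated such reads is not given in the sources used here. Under the same rule, which asks for a mean of at least 10 CPM, the largest falls were those of MANES_01G129800, from 28.9 ± 13.4 to 1.29 ± 0.81 CPM (log2 fold change -4.49, SE 0.55, adjusted p 0.00207), and MANES_02G122700, from 217.8 ± 84.1 to 15.1 ± 3.5 CPM (log2 fold change -3.85, SE 0.31, adjusted p 0.000357). The rise of the chromosome 14 pair was largest in 2 of the libraries with the large top-1000 share: MANES_14G145700 reached 218 and 312 CPM in cold replicates 1 and 3 against 55.7 and 93.6 CPM in cold replicates 2 and 4. In the fit without the 3 libraries with that share, the log2 fold changes were 4.46 for MANES_14G145700, 4.42 for MANES_14G145800 and -5.62 for MANES_01G129800. Every cold library lay outside the range of the control libraries for each of these 4 IDs, which the rule for named IDs requires.

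**Figure D2:**
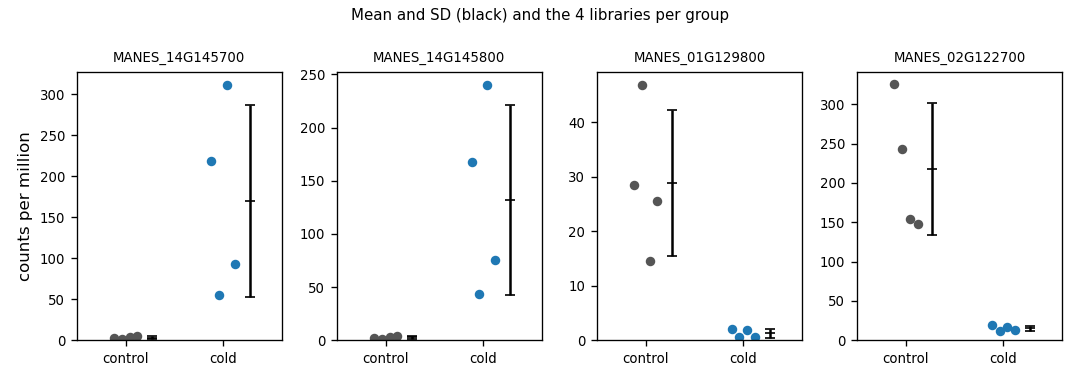
CPM (vertical axis) of 4 IDs in the 4 control and 4 cold libraries, one panel per ID; points are libraries and black bars the mean and SD. In CPM, the 2 IDs on chromosome 14 spread more widely in the cold, and the 2 fallen IDs do so in control. In each case this is the group with the higher mean, so the bars do not compare variability between groups.

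A set of 27 risen IDs had at most 12 counts over the 4 control libraries together. Their summed counts in the 4 cold libraries ranged from 75 to 3154, with a median of 185, and each was above 3 counts in all 4 cold libraries. The count filter asks for a minimum count in at least 4 libraries. IDs this scarce in control could pass it almost only through all 4 cold libraries, so their presence in all 4 is set by the filter. Cold replicate 3 held the highest CPM for 20 of these IDs, cold replicate 1 for 6, cold replicate 4 for 1 and cold replicate 2 for 0. The set held 77 IDs under no filter on low counts, 2 under a filter of at least 1 CPM in 4 libraries and 111 in DESeq2, which also tested more IDs (28336). It held 41 IDs without cold replicate 2 and 16 without the 3 libraries with the large top-1000 share. In the other direction, 4 fallen IDs had at most 12 counts over the 4 cold libraries, with a median of 168 counts summed over the control libraries. This number was 14 in DESeq2, 7 under no filter, 0 under the filter of at least 1 CPM in 4 libraries and 2 in each of the test against a 1.5-fold change and the fit without the 3 libraries.

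None of the 18 chromosomes passed Fisher's exact test for a larger or smaller share of risen or fallen IDs after adjustment over both directions (lowest adjusted p 0.19). The highest share of risen IDs was 5.47%, on chromosome 14, and the highest share of fallen IDs 6.49%, on chromosome 9. Calls of the same direction were neighbours more often than under random placement. In 85 adjacent pairs of tested IDs both members rose, against a mean of 43.59 and a highest value of 72 in 10000 shuffles of the calls. In 138 adjacent pairs both fell, against a mean of 68.47 and a highest value of 107. Both one-sided permutation p-values were 0.0001, the smallest that 10000 shuffles can give. The shuffles, also those of the windows below, treat IDs as independent. Neighbours that vary together or share reads could give more pairs, which was not tested for these pairs. Runs of at least 3 neighbouring tested IDs called in one direction numbered 10 for rises and 18 for falls. On chromosome 2, 4 neighbouring IDs from locus 150800 to 151100 rose with a median log2 change of 3.85, and on chromosome 3, 5 neighbours from locus 151300 to 152100 fell with a median of -2.55. Pair counts moved with the number of calls, from 15 rising and 14 falling pairs in the test against a 1.5-fold change to 312 and 445 in limma-voom with library weights, and the shuffles were not repeated there. Without control replicate 2, 3 or 4 there were 29, 35 and 39 rising and 37, 63 and 77 falling pairs. Without cold replicate 3 or 4 there were 43 and 34 rising and 64 and 47 falling pairs, and without cold replicate 2 there were 77 falling pairs. The shuffled means above hold for 1076 risen and 1349 fallen IDs. Fewer calls give fewer pairs by placement alone, and the fit without control replicate 2 had 477 risen and 589 fallen IDs. The pair counts of these fits therefore cannot be set against those means.

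The densest stretch lay on chromosome 9, where 20 of 33 tested IDs from locus 011300 to 015600 fell and 32 of the 33 had negative log2 fold changes. The median log2 change of the 33 IDs was -0.80, the changes of the 20 fallen IDs ran from -0.57 to -1.30, and the 2 groups of libraries did not overlap for 24 of the 33. Per library, the median log2 level of these IDs over the control mean was 0.19, 0.05, -0.09 and -0.13 in control and -0.67, -0.79, -0.64 and -0.70 in cold replicates 1 to 4. A second stretch on the same chromosome, locus 016800 to 019100, held 8 fallen IDs among 18. The 10 tested IDs between both stretches held 0 fallen IDs and had a median log2 change of 0.08. On chromosome 14, 9 of 21 tested IDs from locus 148000 to 150400 rose, and 4 did so without the 3 libraries with the large top-1000 share. The fullest window of 20 tested IDs held 8 risen IDs, against a highest value of 9 in the shuffles (one-sided permutation p 0.0051). The longer chromosome 9 stretch had 11 fallen IDs without control replicate 2 and 11 without cold replicate 4, 12 without the 3 libraries with the large top-1000 share and 2 in the test against a 1.5-fold change. The shorter one had 3 fallen IDs without control replicate 2, 5 without control replicate 4, 5 without cold replicate 4, 5 without the 3 libraries and 0 in the test against a 1.5-fold change.

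**Figure D3:**
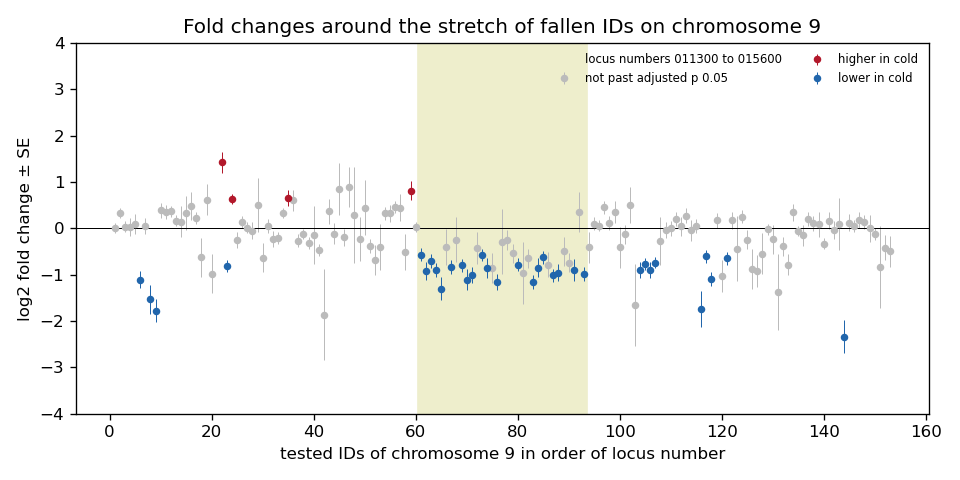
Log2 fold change ± SE (vertical axis) of tested IDs of chromosome 9 in order of locus number (horizontal axis), with the stretch from locus 011300 to 015600 shaded. Blue points are fallen, red points risen and grey points not past an adjusted p of 0.05; 20 of the 33 shaded IDs fell, and 1 ID of the 153 drawn lies outside the vertical axis.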

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

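The comparison of the 35 ways to split the 8 libraries into 4 and 4 was written down after the split counts had been seen. The real split called 2425 IDs and the highest of the other 34 splits called 0, so 1 of 35 splits gave as many. This is the smallest share that the comparison can give. Each of the other 34 splits mixed cold and control libraries on both sides, so a difference between the groups would itself widen their spread. The result argues against chance assignment of the libraries as the origin of the count but cannot exclude it.

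The 10 most abundant IDs, the named IDs, the chromosome 9 stretch, library totals, IDs at 0 and shares in abundant IDs were searched for a library far from the other 3 of its group. This was found in 3 of 38 groups of 4, where chance gives about 1 in 20. The ID of abundance rank 2 reached 6303 CPM in one control library against 4233 to 4403 CPM in the others. The ID of rank 8 reached 5275 CPM in one control library against 2256 to 2516 CPM, and 2301 CPM in one cold library against 1557 to 1654 CPM.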

How the results depend on the processing

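The added alternatives (sva, library weights, 3 libraries left out) were chosen after seeing the data. Over 21 alternatives, 270 of 356 recomputed values stayed on the same side of the threshold or within 1.5 times the count. Most of these are counts, which have no sign to turn; the fold changes of the 4 named IDs and the most abundant ID kept their direction. The 4 named IDs passed in all 21, with log2 fold changes of 4.46 to 5.98 and 4.42 to 5.89 for the risen pair on chromosome 14 and -5.62 to -4.15 and -4.0 to -3.6 for the fallen pair; their highest adjusted p was 0.0228. DESeq2 called 4667 IDs (2282 higher, 2385 lower; 909 and 847 at least 2-fold), among them 2424 of the 2425. limma-voom with library weights called 5049 (2270 higher, 2779 lower; 961 at least 2-fold lower). The cause was not tested for either. glmTreat called 502 (253 higher, 249 lower; 250 and 247 at least 2-fold), since it asks for a larger change. The fit without 3 libraries called 1388 (619 higher, 769 lower; 342 at least 2-fold higher) with fewer samples. Leaving out 1 library gave 1066 (without control replicate 2) to 2356 (without cold replicate 1) IDs, 477 to 971 higher and 589 to 1385 lower, 331 to 580 at least 2-fold higher and 392 to 732 at least 2-fold lower. Without cold replicate 2, higher IDs outnumbered lower ones (945 and 941; 580 and 549 at least 2-fold). Without control replicate 3 the total was 1360, without control replicate 4 1557, without cold replicate 3 1547 and without cold replicate 4 1264.

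Scaling moved the median of all genes by less than 0.1 on the log2 scale, and 38.1% to 47.6% of calls were higher, against 44.4%. No label says that same-numbered libraries share more than a number. Correlations of their deviations from the group means were 0.19, 0.06, -0.29 and -0.08 for replicates 1 to 4. Of the 4 control libraries, 2 were closest to their own number. These values show no factor common to all pairs, but cannot exclude a factor shared by some of them. With the replicate block 1281 IDs were called (592 higher, 689 lower), of which 1194 were among the 2425; the longer chromosome 9 stretch then had 12 fallen IDs, the shorter 3, fallen IDs near 0 in the cold numbered 2, and the most abundant ID an adjusted p of 0.0797. Alternatives set beforehand for gene lists, noncoding genes and antisense pairs were not run, for want of descriptions, biotypes and coordinates. Depth limits the scarce IDs: 3 counts are 0.0478 CPM in the shallowest library.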

Other observations

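The tests of chance placement, copy number and sequencing depth below were written after their results were seen. Cold replicate 3 was picked as the library to test after its peaks had been seen.

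Fallen IDs crowded on chromosome 9. The fullest window of 20 tested IDs held 13 fallen IDs, against a highest value of 10 in 10000 shuffles of the calls (permutation p 0.0001, the smallest they can give). This argues against chance placement of calls that are independent of each other. The shuffles treat IDs as independent, while IDs of this stretch varied together within groups (correlations below). A chance deviation shared by these IDs is therefore not excluded by the shuffles. A single copy-number change spanning both stretches was tested as a log2 change of -0.58 or lower throughout. Of the IDs in the span at 5 CPM or more, 30.8% (12 of 39) had 95% intervals wholly above that loss. A smaller loss was not tested. The span includes the 10 tested IDs between the stretches, already known to hold 0 fallen IDs, so the number largely restates that gap. For the longer stretch alone, tested first, the number was 0 of 18, which met the prediction as first written; after this was seen, the span test was added and the prediction was extended to ask for no raised correlation within groups, which was not met, and since the bounds of the stretch were also drawn from its fallen IDs, a copy-number change there stays open. Deviations from the group means correlated at 0.367 across 27 IDs of the stretch, above 100% of 324 other stretches (highest 0.158), so related genes that vary together or share reads are a candidate explanation, and these cannot be separated without sequences; a joint response to cold also stays open.

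Risen IDs near 0 in control. This was first read from raw counts as a peak in cold replicate 1; in CPM, 20 of 27 IDs peaked in cold replicate 3 and 6 in replicate 1, and the tests were then repeated for replicate 3. A library that reads all scarce IDs higher is argued against for both, since replicate 3 was the highest cold library for 27.6% and replicate 1 for 25% of 2796 unchanged IDs under 1 CPM. With either library left out alone, 25 of 27 IDs were still called higher without replicate 3 and 26 without replicate 1; reliance on the pair stays open, since 26 of the 27 peaks lay in one of them and 16 of the 27 were called without both and control replicate 1, in a fit with fewer samples. A larger response throughout in replicate 3 was not decided. IDs at least 2-fold lower had a median log2 level of -1.31 there against -1.21 in the next lowest library. The difference of -0.10 misses the size set beforehand. IDs at least 2-fold higher had a median of 1.5 in replicate 3, below the 1.54 of replicate 1 but above the 1.08 and 1.23 of replicates 2 and 4. Their rise was thus larger in replicates 1 and 3, and replicate 3 was not the highest.

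Libraries with more counts in their 1000 most abundant IDs. These were control replicate 1, cold replicate 1 and cold replicate 3. The prediction for sequencing depth, lower totals in all 3 than in the other 5 libraries, was not met. Cold replicate 1 had a total above all of the other 5 (100031792 counts), and cold replicate 3 was the shallowest of the 8 (62798223 counts). Control replicate 1 (82385404 counts) was deeper than 1 of the other 5. These totals argue against depth as a single cause shared by the 3 libraries. Depth had first been read as argued against from cold replicate 1. The bound was raised to 2 of the 3 libraries after the result was seen, and by that bound the test was undecided. The 10 most abundant IDs alone are argued against, as a gap of 1.39 percentage points remained without them, against 1.79 with them. No biological explanation was tested.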
